A study of Mus musculus with 2 samples.

How the data were processed

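H3K4me2 was measured by ChIP-seq in livers of B6NCrl mouse embryos at day 13.5, in 2 samples that the labels number as biological replicates of a single group. Both came from embryos of either sex pooled, and the labels name a different tissue sample for each, while the entry for their donor is the same. The spread between them is taken as that between such tissue pools, and p-values here do not measure variation between animals.

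The files used were 4 lists of peaks on mm10: a list per replicate, each called against its own control per the labels, a list called on both replicates together (pooled), and a list of replicated peaks that the labels derive from the other 3. Column 7 of each list held the authors' signal value per peak, never under 1. It was read as enrichment over the control, a meaning that no source used here states. Columns 8 and 9 held the −log10 p and −log10 q that the authors' caller gave each peak. These are the authors' values for a peak and were used only to describe, rank or filter peaks within a list. The aligner, the peak caller, their versions and the thresholds are not given in the sources used here. The lowest −log10 p in the deposited lists was just above 2 (2.01 in the pooled list), as a limit at p = 0.01 would leave it, with no exact statement of one. No number of reads was in the files used, so the depth of each library is unknown, no interval that rests on reads is given, and a weak region missing from a list was not detectable at that depth rather than absent.

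Coordinates are those of the lists, counted from 1, on mm10. The reference was the mouse assembly GRCm38 patch release 6, the same build, with the GENCODE annotation release M21. Protein-coding genes with a protein-coding transcript on the 21 assembled chromosomes were kept. Where several gene entries shared a symbol, that with the most transcripts was kept, which left out 24 entries and kept 21829 genes. Peaks on unplaced or unlocalised sequence entered no comparison with genes.

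Peaks of the replicates were compared by shared bases, at least 1 base in the first instance, and each list was set against 100 seeded moves of its peaks to random places on the same chromosome. Spearman and Pearson correlations of the signal values were taken over shared peaks. Summits were assigned to promoter (within 1 kb of any annotated transcript start), exon, intron or intergenic sequence in that order, and the shares were divided by those of the bases in each class. A gene was marked if a peak lay within 1 kb of any of its protein-coding TSSs. Its breadth was the number of bases covered by peaks within 5 kb of a TSS, for the TSS with the most, which cannot pass the length of the window. Its distal coverage was the number of bases covered within 50 kb and over 1 kb from any protein-coding TSS. Breadth and distal coverage are both assigned by distance alone and can be shared by neighbouring genes. Breadth can take in a peak at the promoter of another gene, and its random lists were not matched on gene density. Bases from 1 to 5 kb can count in both measures. Promoter CpG was the observed over expected frequency within 500 bp of the TSS, the highest of the TSSs of a gene, and genes were ranked on it into 10 bins.

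There were 20 lists of genes: erythroid, embryonic globin, hepatoblast, mature hepatocyte, blood progenitor, megakaryocyte, macrophage, granulocyte and mast cell, lymphoid, endothelial, stellate and mesothelial, cholangiocyte, neural, muscle and heart, epidermis, Hox, housekeeping, cell cycle, germline and olfactory receptor. Of the 339 members named in all lists other than olfactory receptors, 338 were matched to the annotation by symbol, Ahsp of the erythroid list being the exception. Marking was tested with Fisher's exact test, two-sided, against all other protein-coding genes. Median breadth and median distal coverage were set against 10000 seeded random lists of the same size and the same CpG bins, giving a two-sided permutation p of which 0.0002 is the smallest possible. Where matched lists had a median of 0 bp, no list could be called below them, and a list at 0 bp could not be called at all. Unmarked genes can enter at 0 bp, so a median breadth also reflects the share marked. Breadth among marked genes alone was not compared. Each family was adjusted by the Benjamini-Hochberg method over the 20 lists, and an adjusted p under 0.05 was taken as a call, and adjusted values of 0.0008 and 0.00133 stand for lists at that smallest permutation p. Genes are not independent replicates, and these p-values describe the lists of peaks of this tissue.

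Motifs were searched as fixed consensus strings on both strands within 250 bp of summits over 1 kb from any annotated transcript start. They were the composite of CTG and WGATAR 6 to 12 bp apart, WGATAR, and strings for HNF4 (CAAAGTCCA), FOXA (TGTTTAC), HNF1 (GTTAATNATTAA), CEBP (TTGCGCAA), KLF1 (CCMCRCCCN), PU.1 (GAGGAAGT) and CTCF (CCASYAGRKGGC). Control windows were the same windows moved 5 kb to either side, outside pooled peaks and away from transcript starts. Controls matched on GC were instead drawn from seeded random places across the genome, also outside pooled peaks and away from transcript starts. Odds ratios have 95% intervals on the log scale, with Fisher's exact test adjusted over the 9 motifs. The intervals cover counting error only, and windows near each other are not independent.

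The lists, the tests, their windows and most alternative settings were fixed before the data were examined. So was the rule for named genes: the 2 members of each list with the greatest breadth and the 1 with the least, genes at the 10 widest regions, a fixed set of 21 marker genes, and the unmarked members of called lists where there were 5 or fewer. Hba-a2, Neurog2, Dazl and the composite matches were named after their values were seen. A first run of the list tests was looked at before the final version, and the lists counted among the leading results were picked after it. Tests of promoter CpG for the erythroid and hepatoblast lists, of neighbouring Hox genes, of the caller's threshold and of the fold of housekeeping distal coverage beyond 5 kb were chosen after values had been seen. The Hox test took the place of a CpG test whose outcome the matched lists fix by construction, and the threshold test, made on the pooled list, that of the share still marked at a −log10 q of 5 or more, which was high for all genes. The erythroid and hepatoblast CpG test asked only how broad genes of the same CpG were, since these lists had been picked on their breadth. Another 5 alternative settings, 10 further gene groups and the motif positions were also chosen after values had been seen.

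The alternative settings fixed at the start were the pooled list or a replicate alone in place of the replicated list, peaks with a −log10 q of 5 or more, only the first TSS of each gene, TSS windows of 500 bp and 2 kb, breadth windows of 2 and 10 kb, distal windows of 20 and 100 kb, random lists matched or not matched on CpG, other overlaps, joining of peaks within 1 kb, a motif window of 100 bp and controls matched on GC. The 5 added alternatives kept 1 member per 100 kb in each of the 3 list tests, joined peaks within 1 kb for breadth, and began distal coverage at 5 kb.

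Marking, breadth, sums of bases and motifs were tested on simulated data. Distal coverage and marking against matched lists used the same random-list procedure as breadth and were not simulated separately, nor were the other descriptions. Of 10 lists given more marked genes than chance, 10 were called by Fisher's exact test, as was 1 of 10 unchanged lists. The same 10 lists were also widened 3-fold at their marked genes, and 10 were called on breadth, with 0 of 10 unchanged. Marking and breadth were raised together there, so a change in breadth alone, or a smaller one, was not simulated. Sums of bases matched a direct count in all of 1000 windows, and a planted motif was called with 0 of 8 others. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.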

Results

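Livers of mouse embryos at day 13.5, a stage at which the fetal liver is the main site of blood formation as well as a growing hepatic epithelium, were profiled for dimethylated lysine 4 of histone H3 (H3K4me2), a mark found at active and primed promoters and enhancers. The series held 2 biological replicates of 1 group, each from strain B6NCrl and from male and female embryos pooled, with different tissue samples behind them. Peaks had been called in each replicate, on both replicates together (the pooled list), and as a list of replicated peaks, which was used as the set of H3K4me2 regions unless another list is named. With 1 group, the comparisons were between the replicates, between classes of sequence, and between groups of genes within this tissue. Sequencing depth was not given in the files used here and is unknown, so no difference between the lists could be set against depth.

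H3K4me2 covered 62.2 Mb of the genome in 41382 replicated peaks, or 2.35% of the assembled chromosomes, with a median width of 1040 bp. Replicate 1 had 54584 peaks over 57.5 Mb and replicate 2 had 53065 peaks over 58.1 Mb, a mean of 53824.5 ± 1074 peaks (SD, n = 2) with a median width of 591.5 ± 36.1 bp. The pooled list held 59629 peaks. The strongest of the replicated peaks by the authors' signal value, at 80.4, lay at Runx1, a transcription factor required for blood stem cell formation, on chromosome 16 at 92692755 to 92700991 (mm10). The X chromosome carried 1037 replicated peaks and the Y chromosome 7.

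The replicates placed the mark at largely the same regions. Of the peaks of replicate 1, 81.1% shared at least 1 base with a peak of replicate 2, and 82.2% the other way, against 4.02% and 4.06% when peaks were moved to random places on their chromosomes. The highest of the 100 random moves gave 4.20% and 4.30%. Bases covered in both made up a Jaccard index of 0.786. Across the 44244 shared peaks of replicate 1, the signal values of both replicates correlated with a Spearman rho of 0.819 and a Pearson r of 0.862, which describe agreement across regions that are not independent replicates.

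Regions present in a single replicate were narrow, weak and mostly away from promoters. Of the 10327 peaks found only in replicate 1, 10.2% lay within 1 kb of the transcription start site (TSS) of a protein-coding gene, against 40.9% of its shared peaks, and of the 9436 found only in replicate 2, 10.1% did, against 41.0%. Their median widths were 220 bp and 239 bp, where shared peaks measured 811 bp and 846 bp. A −log10 q of 5 or more was reached by 11.5% and 14.3% of them, and by 76.5% and 80.5% of shared peaks. No test was made of these differences, since neighbouring peaks of a library are not independent.

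All 41370 replicated peaks on the assembled chromosomes had the same coordinates as a peak of the pooled list, so their edges and values came from the replicates called together. In 78.7% of them at least 50% of the peak was covered by a peak of each replicate, and 92.6% met that level when the share was taken of either the pooled or the replicate peak. The remaining 3069 met neither form, and 74 replicated peaks touched no peak of either replicate. At Lor, which encodes a cornified envelope protein, a replicated peak of signal 25.4 reached the 1 kb TSS window although neither replicate had a peak in that window. Both replicates did have bases covered within 5 kb of the Lor TSS, given below with the epidermal genes.

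Promoters held most of the mark relative to their length. Summits fell within 1 kb of a TSS in 45.4% of replicated peaks, 7.50 times the share expected from the bases in that class, and in exons in 5.13%, 1.61 times the expected share. Introns held 31.1% of summits (0.810 times) and sequence between genes 18.4% (0.351 times). Of 21829 protein-coding genes, 14748 (67.6%) had a replicated peak within 1 kb of a TSS, termed marked below. The share was 67.9% in replicate 1 and 68.0% in replicate 2, with 14659 genes marked in both and 330 in a single replicate. Bases covered within 5 kb of the TSS, termed breadth, had a rho of 0.991 between replicates across genes, which are not independent replicates, and a median SD of 127 bp among marked genes. Breadth counts every peak in the window, so the value of a gene can include peaks at the promoter of a neighbour.

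Marking followed promoter CpG content. Genes were ranked by the observed over expected frequency of CpG within 500 bp of the TSS. In the lowest decile 3.34% of genes were marked, in decile 4 55.7%, in decile 5 89.1% and in the highest 99.4%. Median breadth was 0 bp in the lowest 3 deciles and 3892.5 bp in the highest. The gene groups below were for this reason also set against random lists drawn from the same CpG deciles.

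**Figure D1:**
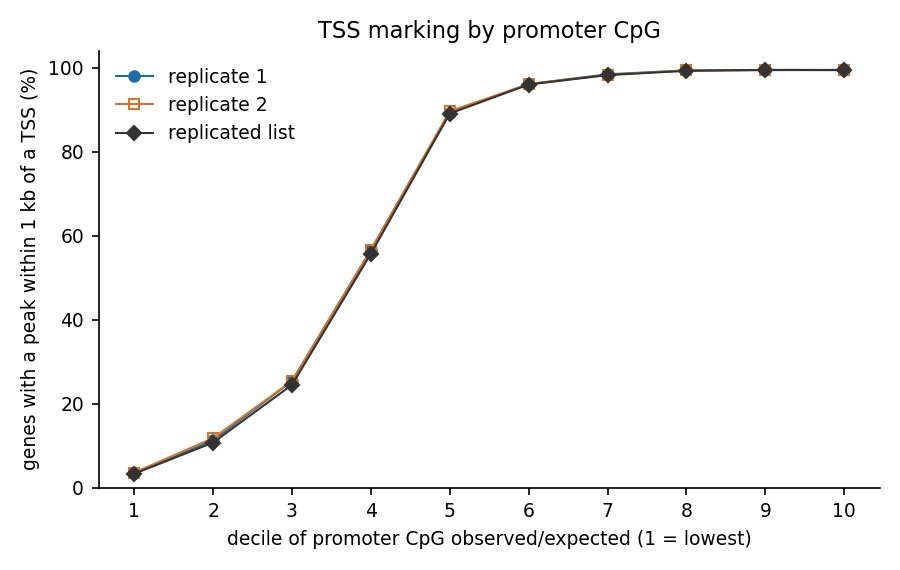
Percentage of protein-coding genes with a peak within 1 kb of a TSS (vertical axis) in each decile of promoter CpG observed over expected (horizontal axis, 1 lowest), for each replicate and the replicated list. The points of the lists lie nearly on top of each other, rising from 3.34% in the first decile of the replicated list to 99.4% in the last.

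Erythroid genes carried H3K4me2 at their promoters, and most of them broadly. All 27 erythroid genes matched to the annotation were marked at 1 TSS or more in the replicated list and in each replicate, against 67.5% of other genes, and 96.3% were marked when only the first TSS of each gene was used. Ank1, encoding the red cell ankyrin that anchors the membrane skeleton, had 9948 bp covered within 5 kb of a TSS (9569 ± 144 bp, SD, n = 2), Nfe2, a transcription factor acting at globin genes, 9905 bp (9892 ± 26.2 bp), and Tal1, a master regulator of blood formation, 9677 bp (9653 ± 42.4 bp). Gata1, the transcription factor that directs red cell differentiation, had 9359 bp (8708 ± 599 bp) and Klf1, an activator of adult beta-globin, 6155 bp (6034 ± 122 bp, chromosome 8 at 84899837 to 84905507, across the TSS). Median breadth of the group was 7309 bp, 7132 ± 129 bp in the replicates (SD, n = 2), against 0 bp in random lists of like CpG. Part of this gap can come from the lower share marked in those lists.

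The distal surroundings of the erythroid genes were covered as well. Bases from 1 to 5 kb count in both breadth and distal coverage, so the measures overlap, but the distal call was kept with coverage begun at 5 kb. Between 1 and 50 kb from the TSS, and over 1 kb from any protein-coding TSS, a median of 13417 bp was covered, 12604 ± 208 bp in the replicates (SD, n = 2), against 1181 bp in matched random lists. Ank1 had 37834 bp, Tal1 19930 bp and Klf1 12881 bp. The group's marking differed from that of other genes (Fisher's exact test, two-sided, adjusted p = 0.000241) and from that of random lists of like CpG, in which a median of 44.4% of members were marked (permutation adjusted p = 0.0008). Its breadth (permutation adjusted p = 0.0008) and distal coverage (permutation adjusted p = 0.00133) were above those of matched lists, each at p = 0.0002 before adjustment, the smallest the 10000 random lists can give.

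The globin genes differed among themselves in extent. Hba-a2 and Hba-a1, the adult alpha-globin genes, had 8616 bp (8262 ± 78.5 bp, SD, n = 2) and 6706 bp (6684 ± 159 bp) covered around the TSS. Hbb-bt and Hbb-bs, the adult beta-globin genes, had 5749 bp (5378 ± 434 bp) and 2505 bp (2561 ± 648 bp). Of the embryonic globins, Hbb-bh1 had 1343 bp (841.5 ± 497 bp, SD, n = 2), and Hba-x and Hbb-y were unmarked in the replicated list and had a TSS peak in replicate 1 only. The distal windows of Hbb-bs, Hbb-bh1 and Hbb-y took in the same 15015 bp of covered sequence. Both the adult alpha and the adult beta genes are near-identical pairs, and reads that fit either copy leave their individual values uncertain.

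As a group, the embryonic globins had a median breadth of 1343 bp against 0 bp in matched lists (permutation adjusted p = 0.0276) and a median distal coverage of 15015 bp against 0 bp (permutation adjusted p = 0.0032). The distal median was the 15015 bp that the windows of Hbb-bh1 and Hbb-y both took in. Random lists were drawn gene by gene, so that call counts the same covered bases more than once. Marking in 1 of 3 members, 3 of 3 in replicate 1, did not differ from other genes (Fisher's exact test, adjusted p = 0.330). The median breadth was the value of Hbb-bh1, and with replicate 1 alone the group's median breadth was 490 bp (permutation adjusted p = 0.0680). With 1 member kept per 100 kb, 2 members remained, with 1577.5 bp, and the breadth call ended (permutation adjusted p = 0.192). Within 2 kb of the TSS the median of the group was 0 bp. Against unmatched random lists the value of 1343 bp lay below the random median (permutation adjusted p = 0.742).

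**Figure D2:**
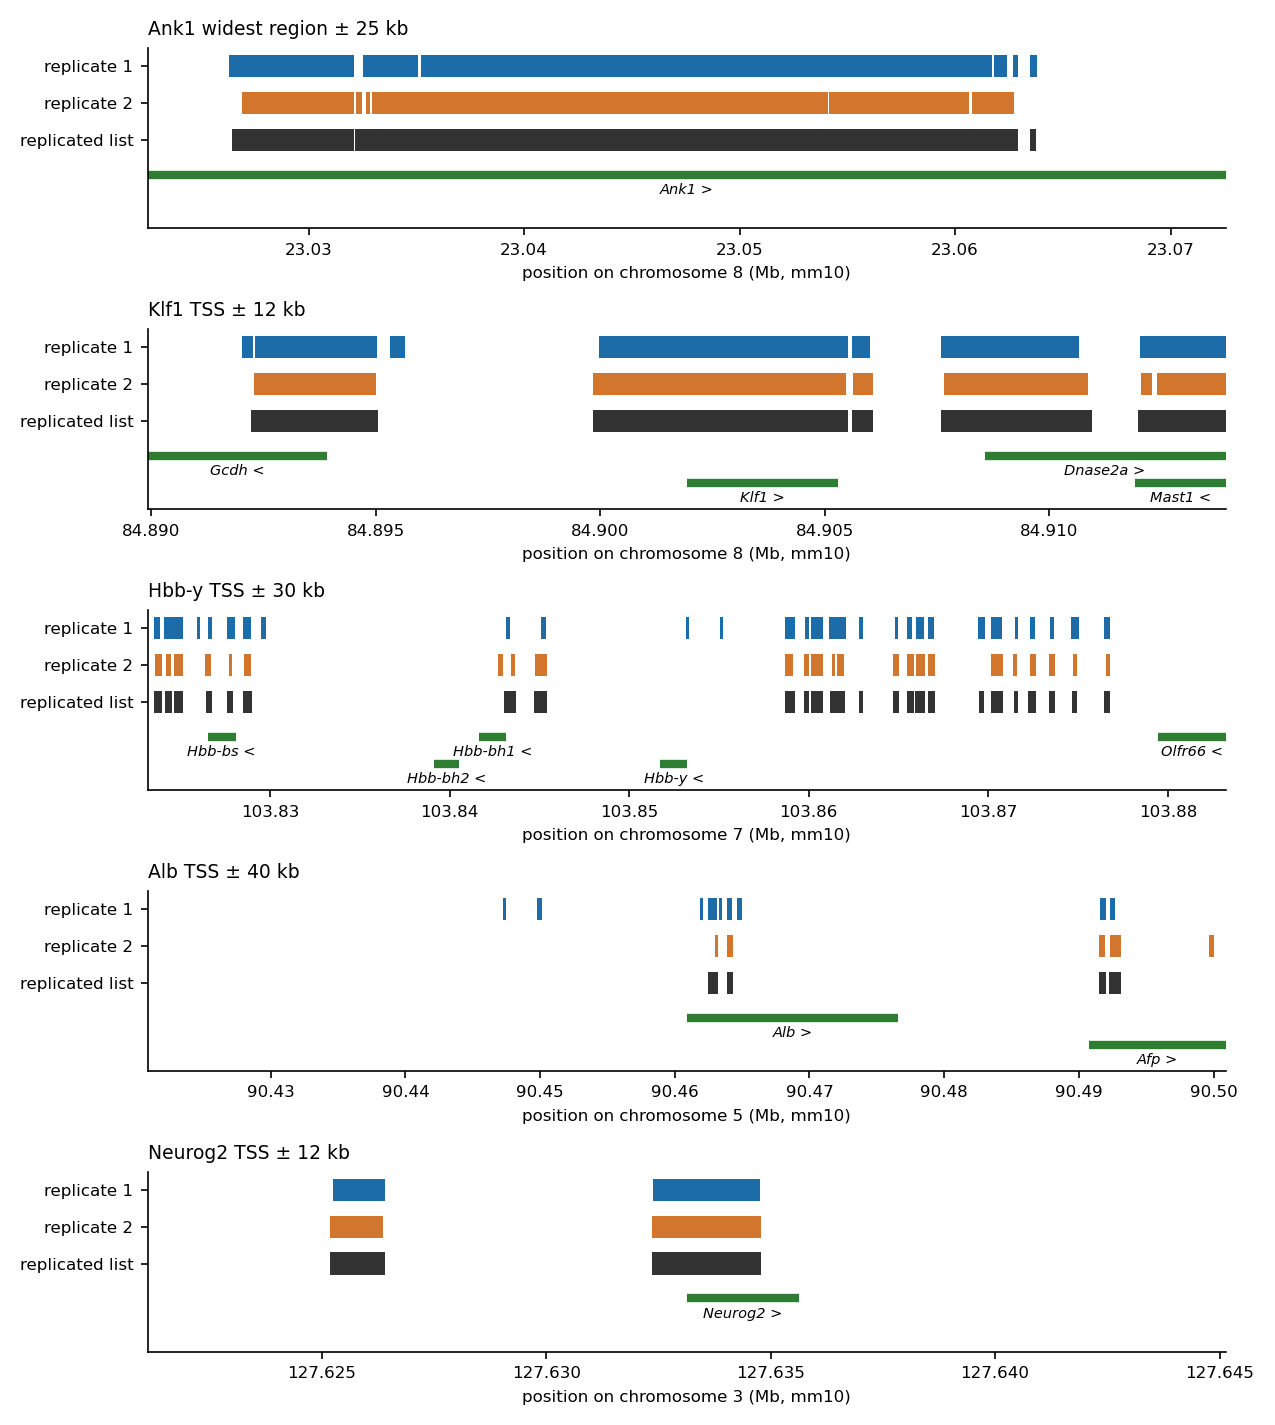
Peaks of each replicate and of the replicated list (bars) along the chromosome (horizontal axis, Mb, mm10) at the Ank1, Klf1, Hbb-y, Alb and Neurog2 loci, with genes in green and arrowheads for the direction of transcription. The widest region, at Ank1, spans 30752 bp, while Alb carries short peaks inside the gene and Hbb-y has a peak at its TSS in replicate 1 only.

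**Figure D3:**
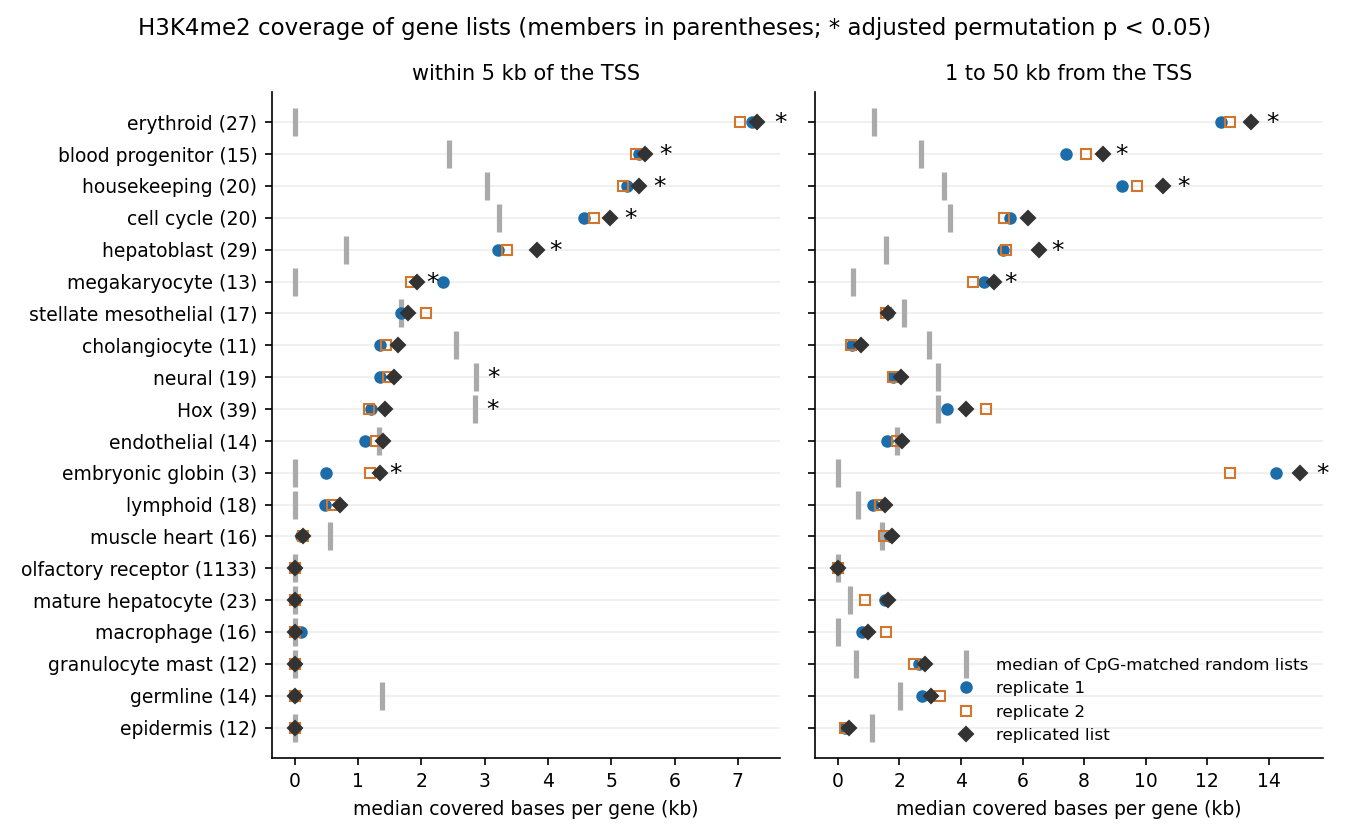
Median covered bases per gene (kb) within 5 kb of the TSS (left) and between 1 and 50 kb (right) for each gene group, in each replicate (circles and squares) and the replicated list (diamonds), with the median of CpG-matched random lists as a grey bar and an asterisk where the adjusted permutation p was under 0.05. Erythroid genes reach 7309 bp around the TSS where matched lists have 0 bp, and in the left panel neural and Hox genes lie to the left of their bars.

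Genes of the hepatoblast, the fetal precursor of hepatocytes and bile duct cells, carried the mark at a promoter in 25 of 29 cases, with 28 in replicate 1 and 27 in replicate 2. Prox1, a transcription factor of hepatoblast migration, had 8201 bp covered (8168 ± 67.2 bp, SD, n = 2) and Apom, an apolipoprotein, 7044 bp (6692 ± 221 bp). Hnf4a, the central transcription factor of hepatic differentiation, had 3565 bp (3284 ± 96.9 bp), with a peak of signal 9.42 at 163547924 to 163550703 on chromosome 2. Plasma protein genes of the group varied in extent: F2 had 4898 bp, Fgg 4008 bp and Afp, encoding alpha-fetoprotein, 1413 bp (991.5 ± 318 bp). Alb, encoding albumin, had 1171 bp (1226 ± 769 bp), with a TSS peak in replicate 1 only. The other unmarked members were Apob, Fgb and Kng1, each with covered bases within 5 kb (2466, 1842 and 507 bp) and with a TSS peak in at least 1 replicate.

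Hepatoblast genes had a median breadth of 3826 bp, 3284 ± 96.9 bp in the replicates (SD, n = 2), against 814 bp in matched lists, and a median distal coverage of 6551 bp against 1574 bp. Marking in 86.2% of members was above the 67.5% of other genes (Fisher's exact test, adjusted p = 0.0459) and above the 51.7% of matched lists (permutation adjusted p = 0.0008). Breadth (permutation adjusted p = 0.0008) and distal coverage (permutation adjusted p = 0.00133) were also above matched lists. With the TSS window narrowed to 500 bp, 75.9% of members were marked and the call against all other genes ended (Fisher's exact test, adjusted p = 0.443). In the pooled list 100% were marked (Fisher's exact test, adjusted p = 0.00026).

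Genes of the mature hepatocyte were mostly unmarked, 7 of 23 carrying a peak at the TSS. Marked members included Pah and Fah, enzymes of phenylalanine and tyrosine breakdown, with 3688 bp (3184 ± 281 bp, SD, n = 2) and 3027 bp (2759 ± 83.4 bp) covered. Cps1, the first enzyme of the urea cycle, and Cyp2e1, a drug-metabolising cytochrome P450, had no covered base around the TSS and none in the distal window, in the replicated list or either replicate. The share marked was below that of other genes (Fisher's exact test, adjusted p = 0.00145) but not different from matched lists, at 30.4% against 26.1% (permutation adjusted p = 0.938). Median breadth was 0 bp, as in matched lists (permutation adjusted p = 1.00), and distal coverage was 1622 bp against 395.5 bp (permutation adjusted p = 0.263), with 1523 bp in replicate 1 and 895 bp in replicate 2. The difference between the hepatoblast and mature hepatocyte groups was not tested.

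Genes of blood stem and progenitor cells were broadly covered, with 14 of 15 marked. Runx1 had 8778 bp covered (8264 ± 362 bp, SD, n = 2), Meis1, a homeodomain factor of stem cell maintenance, 7846 bp (7855 ± 157 bp), and Spi1, encoding the myeloid and lymphoid factor PU.1, 3271 bp (3154 ± 510 bp). Mpl, the thrombopoietin receptor, was unmarked in the replicated list and had a TSS peak in replicate 2 only. The median was 5528 bp, 5413 ± 26.9 bp in the replicates, against 2441.5 bp in matched lists (permutation adjusted p = 0.0008), and distal coverage was 8612 bp against 2719 bp (permutation adjusted p = 0.0032). Marking did not differ from matched lists, at 93.3% against 80% (permutation adjusted p = 0.262). Nor did it pass against all other genes (Fisher's exact test, adjusted p = 0.0694), although in 5 of the alternative settings it did, among them replicate 2 alone, where all members were marked (Fisher's exact test, adjusted p = 0.00714). At 100 kb the distal call ended, at 9956 bp (permutation adjusted p = 0.194).

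Of 13 megakaryocyte genes, 8 were marked. Fli1, a transcription factor of megakaryocytes and endothelium, had 6730 bp (6161 ± 31.1 bp, SD, n = 2) and Itga2b, the platelet integrin alpha IIb, 4962 bp (4259 ± 97.6 bp), while Vwf, Gp6, Pf4, Ppbp and Selp were unmarked. Breadth was 1924 bp against 0 bp in matched lists (permutation adjusted p = 0.0125) and distal coverage 5070 bp against 501 bp (permutation adjusted p = 0.0180). The share marked was above matched lists, at 61.5% against 30.8% (permutation adjusted p = 0.0287), and did not differ from that of all other genes (Fisher's exact test, adjusted p = 0.821). With unmarked genes entering mostly at 0 bp, the breadth call can largely repeat this difference in marking. The breadth call ended in a 10 kb window (permutation adjusted p = 0.0644) and against unmatched lists (permutation adjusted p = 0.852), and the distal call when bases within 5 kb of a TSS were left out (permutation adjusted p = 0.269) or against unmatched lists (permutation adjusted p = 0.188).

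Marker genes of mature white cells had the mark at few promoters. Among macrophage genes 5 of 16 were marked: Cd68, a lysosomal glycoprotein, had 5957 bp in its window (5360 ± 475 bp, SD, n = 2), Mafb, a transcription factor of macrophages, 4824 bp (4484 ± 92.6 bp), and Adgre1, the F4/80 antigen, 0 bp. Among granulocyte and mast cell genes only Prtn3, the neutrophil protease 3, was marked of 12, with 6027 bp (5514 ± 120 bp), and Elane, neutrophil elastase beside it, had 2439 bp (2266 ± 120 bp) and no TSS peak in the replicated list. In the single replicates 2 and 3 of these 12 genes were marked. Among lymphoid genes 7 of 18 were marked: Ebf1, a B cell factor, had 4223 bp (3682 ± 128 bp), Lck, a T cell kinase, 3159 bp (3221 ± 481 bp), and Blk, a B cell kinase, and Cd19, the B cell co-receptor, 0 bp.

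The shares marked were below that of other genes for macrophage (31.2%, adjusted p = 0.0112), granulocyte and mast cell (8.33%, adjusted p = 0.000241) and lymphoid genes (38.9%, adjusted p = 0.0361) in Fisher's exact test. None of these 3 groups differed from random lists of like CpG, whose medians were 18.8%, 25% and 27.8% (permutation adjusted p = 0.463, 0.545 and 0.743). Median breadths were 0, 0 and 717 bp against 0 bp for each group's matched lists (permutation adjusted p = 1.00, 1.00 and 0.0856). Distal coverage was 987.5, 2834 and 1547 bp against 0, 578.5 and 641 bp (permutation adjusted p = 0.351, 0.200 and 0.452). With replicate 1 alone the lymphoid breadth was 476.5 bp and the macrophage breadth 90 bp, and with replicate 2 alone the macrophage distal coverage was 1560.5 bp. In the pooled list the macrophage breadth was 259 bp (permutation adjusted p = 0.0360).

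None of the groups of the other resident cell types of the liver passed a test at the settings used. Of 14 endothelial genes 9 were marked, with 2848 bp (1994 ± 677 bp, SD, n = 2) at Stab1, a scavenger receptor of sinusoids, 2561 bp (2038 ± 176 bp) at Kdr, a receptor for vascular endothelial growth factor, 2106 bp (1368 ± 482 bp) at Pecam1, a junctional adhesion molecule, and 0 bp at Emcn, a sialomucin. Of 17 stellate and mesothelial genes 13 were marked, with 8253 bp (7399 ± 321 bp) at Reln, encoding reelin, and 6190 bp (5274 ± 275 bp) at Lhx2, a transcription factor of stellate cells, and 0 bp at Col3a1, a fibrillar collagen. Of 11 cholangiocyte genes 8 were marked, with 5882 bp (5864 ± 267 bp) at Sox4 and 4579 bp (4396 ± 215 bp) at Sox9, transcription factors of the bile duct, and 0 bp at Krt7, a duct keratin.

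Median breadth in the endothelial, stellate and mesothelial, and cholangiocyte groups was 1392, 1783 and 1628 bp against 1328, 1672 and 2544 bp in matched lists (permutation adjusted p = 1.00, 1.00 and 0.187). Distal coverage was 2090, 1638 and 769 bp against 1922, 2166 and 2950 bp (permutation adjusted p = 0.931, 0.734 and 0.135), the cholangiocyte value being 465 bp in replicate 1 and 436 bp in replicate 2. Shares marked were 64.3%, 76.5% and 72.7% (Fisher's exact test, adjusted p = 0.821, 0.757 and 1.00), and also did not differ from matched lists (permutation adjusted p = 0.938, 0.379 and 0.743). Within 2 kb of the TSS, cholangiocyte breadth was below matched lists at 1054 bp (permutation adjusted p = 0.0275), and distal coverage within 20 kb was below them at 48 bp (permutation adjusted p = 0.0470).

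Neural and Hox genes were mostly marked, and narrowly. Of 19 neural genes 18 carried a TSS peak, all but Stmn2, a neuronal tubulin regulator. Gfap, the astrocyte filament protein, had 4418 bp (4230 ± 315 bp, SD, n = 2), Pax6, a factor of eye and brain development, 4310 bp (3610 ± 107 bp), Neurod1, a neuronal differentiation factor, 1374 bp (1216 ± 72.1 bp), and Neurog1, a proneural factor, 363 bp (326.5 ± 50.2 bp). Of 39 Hox genes, which pattern the body axis, 28 were marked, with 5466 bp (5237 ± 410 bp) at Hoxa2, 4990 bp (4876 ± 65.8 bp) at Hoxa1 and 0 bp at Hoxa11.

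Neural genes had a median breadth of 1573 bp, 1408 ± 84.1 bp in the replicates (SD, n = 2), against 2864 bp in matched lists (permutation adjusted p = 0.00286). Hox genes had 1428 bp, 1184 ± 17.7 bp in the replicates, against 2848 bp (permutation adjusted p = 0.0008). The neural share marked, 94.7%, was above that of all other genes (Fisher's exact test, adjusted p = 0.0233) and not different from the 89.5% of matched lists (permutation adjusted p = 0.938). The Hox share, 71.8%, was below the 92.3% of matched lists (permutation adjusted p = 0.0008) and not different from all other genes (Fisher's exact test, adjusted p = 0.821). Distal coverage was 2063 bp for neural and 4171 bp for Hox genes against 3270 and 3254 bp (permutation adjusted p = 0.389 and 0.452).

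Hox genes lie side by side in 4 clusters, and with 1 member kept per 100 kb the 6 remaining had 1745.5 bp against 3054.5 bp, which did not pass (permutation adjusted p = 0.101). Of these 6, 66.7% were marked. That share was not set against matched lists, so the low Hox share there can also rest on neighbouring genes. The Hox breadth call also ended in a 10 kb window (permutation adjusted p = 0.0542), and both breadth calls ended against unmatched lists (permutation adjusted p = 0.644 for neural and 0.328 for Hox genes). The neural marking call ended when only the first TSS of each gene was used, at 84.2% (Fisher's exact test, adjusted p = 0.134).

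Muscle and heart, epidermal, germline and olfactory receptor genes had few marked promoters. Of 16 muscle and heart genes 4 were marked, with 2769 bp (2564 ± 117 bp, SD, n = 2) at Tnni3, cardiac troponin I, 1571 bp (1502 ± 26.9 bp) at Ryr2, the cardiac calcium release channel, and 0 bp at Myod1, the muscle determination factor, and Ckm, muscle creatine kinase. Of 12 epidermal genes 4 were marked, with 2208 bp (1810 ± 454 bp) at Perp, a desmosomal protein, 2114 bp (1910 ± 84.9 bp) at Lor and 0 bp at Dsg3, a desmoglein. Of 14 germline genes Dppa3, a maternal factor of early development, with 1210 bp (1157 ± 73.5 bp), and Dazl, a germ cell RNA-binding protein, were marked. Tnp2, a sperm transition protein, had 3174 bp (3056 ± 105.4 bp) in its window but no TSS peak, and Ddx4, a germ cell helicase, had 0 bp.

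Of 1133 olfactory receptor genes, which are expressed in sensory neurons of the nose, 4 (0.353%) were marked, against 71.2% of other genes and 13.8% in matched lists, an odds ratio of 0.00143. Olfr56 had the broadest cover, 3642 bp (3714 ± 494 bp, SD, n = 2), then Olfr94 with 1126 bp (760.0 ± 15.6 bp). The olfactory share was below matched lists (permutation adjusted p = 0.0008), as was the germline share, 14.3% against 64.3% (permutation adjusted p = 0.0008). Against all other genes the shares were also low for germline (adjusted p = 0.000302), muscle and heart (25%, adjusted p = 0.00149) and epidermal genes (33.3%, adjusted p = 0.0413) in Fisher's exact test. The latter pair did not differ from matched lists, at 50% and 41.7% (permutation adjusted p = 0.122 and 0.938), and with 1 member per 100 kb the epidermal call ended (Fisher's exact test, adjusted p = 0.0694).

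Median breadth was 121.5 bp for muscle and heart and 0 bp for epidermal, germline and olfactory genes, against 561, 0, 1376 and 0 bp (permutation adjusted p = 0.746, 1.00, 0.0916 and 1.00). For epidermal and olfactory genes the reference of 0 bp left no lower value, so their breadth test decided nothing. Distal coverage in the same order was 1758, 354.5, 3032 and 0 bp against 1439, 1096, 2032 and 0 bp (permutation adjusted p = 0.837, 0.555, 0.565 and 1.00), the epidermal value being 227 bp with replicate 2 alone. With 1 member per 100 kb, germline breadth of 0 bp was below matched lists (permutation adjusted p = 0.0485).

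Housekeeping and cell cycle genes were each marked at 1 TSS or more, 20 of 20 in both groups, and with only the first TSS of each gene 95% of housekeeping and 100% of cell cycle genes were marked. Hmbs, the third enzyme of heme synthesis, had 9817 bp (9710.5 ± 46.0 bp, SD, n = 2) and Tubb5, a beta-tubulin, 9068 bp (8772 ± 10.6 bp). Gapdh, a glycolytic enzyme, had 6589 bp (6049 ± 440 bp), Actb, cytoplasmic actin, 6535 bp (5895 ± 419 bp), and Gusb, a lysosomal glucuronidase, 2573 bp (2520 ± 153 bp). In the cell cycle group Mcm2, a subunit of the replicative helicase, had 7727 bp (7436 ± 298 bp), Pcna, the replication clamp, 6830 bp (6414.5 ± 9.19 bp), and Bub1, a spindle checkpoint kinase, 2554 bp (2410.5 ± 6.36 bp).

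Median breadth was 5434.5 bp in housekeeping genes against 3039 bp in matched lists (permutation adjusted p = 0.0008) and 4985.5 bp in cell cycle genes against 3223.5 bp (permutation adjusted p = 0.00267). Distal coverage was 10574.5 bp in housekeeping genes against 3466 bp (permutation adjusted p = 0.00133) and 6176 bp in cell cycle genes against 3656 bp (permutation adjusted p = 0.181). Both shares marked were above that of all other genes (Fisher's exact test, adjusted p = 0.00145), and matched lists also had a median of 100% (permutation adjusted p = 1.00). With bases within 5 kb of a TSS left out, housekeeping distal coverage was 1798 bp against 709 bp, a fold of 2.54 where it had been 3.05, and did not pass (permutation adjusted p = 0.236). In a 10 kb window the cell cycle breadth did not pass (permutation adjusted p = 0.0505), whereas its distal coverage did at 20 kb (permutation adjusted p = 0.0297).

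Over the 20 groups, marking was above that of all other genes in 5 and below it in 8, and against CpG-matched lists above in 3 and below in 3. Breadth was above matched lists in 7 groups and below in 2, and distal coverage above in 6 and below in 0. At an unadjusted permutation p under 0.05, distal coverage was below in 1, the cholangiocyte group (p = 0.0474).

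The widest replicated regions lay at Ank1 and Zfpm1, both genes of the erythroid group. The widest, 30752 bp on chromosome 8 at 23032176 to 23062927, lay inside Ank1 and held at least 1 of its annotated TSSs. It was covered over 29934 bp in replicate 1 in 4 pieces and over 30111 bp in replicate 2 in 5 pieces. The region at Zfpm1, encoding the GATA1 cofactor FOG1, spanned 29127 bp on chromosome 8 at 122282125 to 122311251, and that at Rbm38, an RNA-binding protein, 19950 bp on chromosome 2. A region of 17066 bp on chromosome 8 held the TSSs of Junb, Prdx2, a peroxiredoxin abundant in red cells, and Rnaseh2a. Next were Epb41, the red cell protein 4.1, with 15777 bp, St3gal5, a ganglioside synthase, with 15654 bp, Sema4b with 15029 bp, Galnt10 with 14945 bp, Kdm6b, an H3K27 demethylase, with 14185 bp, and Steap3, an iron reductase of erythroid cells, with 14156 bp.

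In all, 63 replicated regions reached 10 kb, against 33 in replicate 1 alone and 39 in replicate 2 alone. Joining peaks within 1 kb of each other raised the number to 251, and the widest joined region, 51232 bp, lay at Zfpm1 rather than Ank1, which came next with 37340 bp.

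Summits near promoters lay mostly downstream of the TSS. Of 18314 replicated summits within 2 kb of a protein-coding TSS, 72.2% were on the transcribed side, with a median position of 219 bp into the gene and quartiles at −56 bp and 541 bp. The share downstream was 69.3% in replicate 1 and 70.0% in replicate 2. Between 200 and 1500 bp from the TSS, 47.6% of these summits lay downstream and 18.2% upstream.

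**Figure D4:**
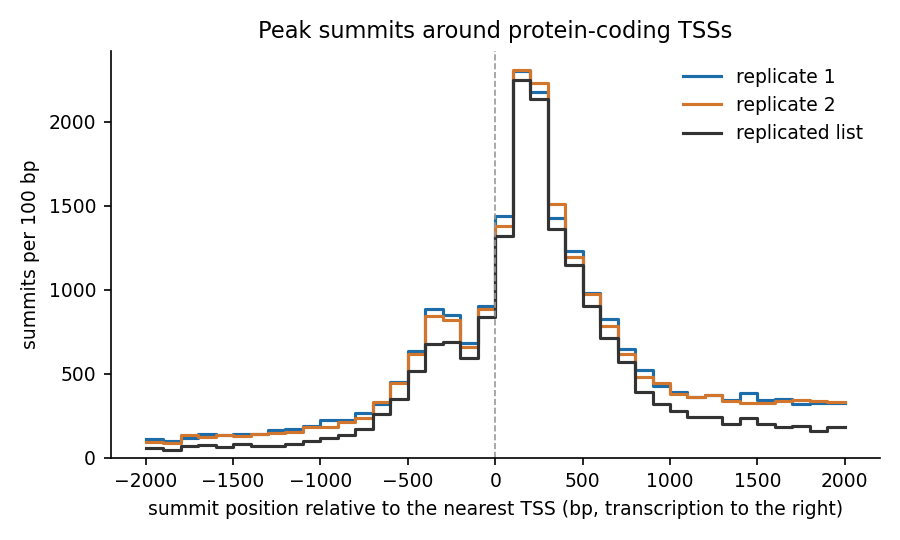
Number of peak summits per 100 bp (vertical axis) by distance from the nearest protein-coding TSS (horizontal axis, bp, transcription to the right) in each replicate and the replicated list. The larger peak stands downstream of the TSS and a smaller one upstream, and 72.2% of replicated summits within 2 kb are downstream.

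Windows of 250 bp each side of distal summits carried 8 of the 9 motifs searched more often than moved windows did. A summit was distal if over 1 kb from any annotated transcript start, though its peak could still reach one. At 22586 distal summits, the composite of an E-box CTG and a GATA site, bound in red cells by TAL1 with GATA1, was present in 19.5% against 12.1% of 34283 windows moved 5 kb away (odds ratio 1.76, 95% interval 1.68 to 1.84). The KLF1 motif was present in 28.6% against 14.3% (odds ratio 2.40, 2.3 to 2.5), the PU.1 motif in 4.65% against 3.19% (1.48, 1.36 to 1.61), and the GATA site alone in 63.2% against 59.9% (1.15, 1.11 to 1.19). Among liver factors, the CEBP motif had an odds ratio of 3.04 (1.6 to 5.77), that of HNF4 1.29 (1.07 to 1.56) and that of FOXA 1.21 (1.14 to 1.29), with 0.124%, 0.868% and 7.90% of summits. The motif of CTCF, a protein of domain boundaries, was present in 2.13% against 0.429% (5.06, 4.21 to 6.10).

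In Fisher's exact test, 8 of the 9 motifs were above the moved windows, HNF4 at an adjusted p of 0.0110 and the composite at 2.28e-125, and HNF1 was not (odds ratio 1.92, 0.977 to 3.79, adjusted p = 0.0779). Within 100 bp of the summit 4 were above: the composite, KLF1, PU.1 and CEBP. There HNF4 (odds ratio 1.26, adjusted p = 0.190) and FOXA (1.04, adjusted p = 0.444) did not pass Fisher's exact test, and GATA (0.837) and CTCF (0.484) were below the moved windows. The moved windows had a lower GC content, 44.7% against 49.1% in the 250 bp windows and 44.7% against 51.2% in the 100 bp windows. No GC-matched controls were run at 100 bp, so whether the low GATA and CTCF values there rest on GC was not tested. With controls matched on GC at 250 bp, the odds ratio rose to 1.49 for GATA, 1.45 for FOXA and 1.84 for the composite, and fell to 1.89 for KLF1 and 4.62 for CTCF. There CEBP, in 28 against 15 windows, did not pass (odds ratio 1.87, Fisher's exact test, adjusted p = 0.0659). HNF1, in only 19 against 4 windows, did (odds ratio 4.75, Fisher's exact test, adjusted p = 0.00333). These controls came from random places in the genome rather than nearby, so the changes cannot be put down to GC alone.

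Of the peaks with a distal summit and a composite match, those with the highest signal included a peak with its summit in an exon of Tsc22d4. It lay on chromosome 5 at 137744866 to 137749887 (signal 63.4), with the match CTGGGACTGGAGATAG 27 bp from the summit. An intronic summit in Zfpm1 on chromosome 8 (signal 61.3) had CTGGTGGCCGTAGATAA on the minus strand at 122284836 to 122284852. An intronic summit in Stx2, of a peak on chromosome 5 at 128999937 to 129008591, had a signal of 57.8. These summits lay 1693 bp (Tsc22d4), 2506 bp (Zfpm1) and 1677 bp (Stx2) from the nearest protein-coding TSS, and each peak reached across that TSS.

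**Figure D5:**
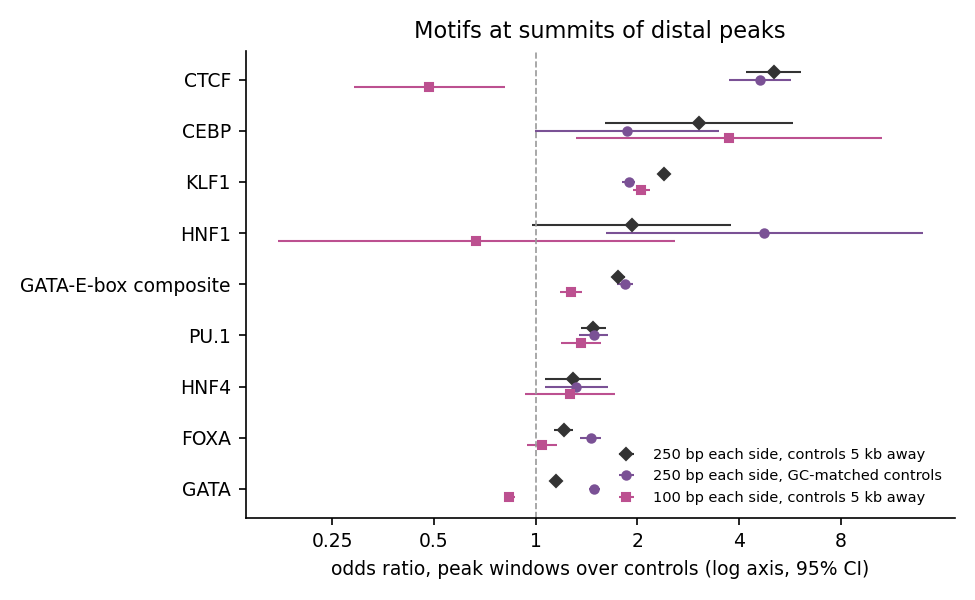
Odds ratio of each motif in windows at distal summits over control windows (horizontal axis, log scale, bars are 95% intervals), for windows of 250 bp with controls 5 kb away, the same with GC-matched controls, and windows of 100 bp. CTCF lies at 5.06 in the wide window and 0.484 in the narrow one, and GATA at 1.15 and 0.837.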

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

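No test in this part was chosen after the result was seen, and both results below concern peaks left out of the main set of replicated peaks on assembled chromosomes, with no control samples to set them against. Of the replicated peaks, 12 lay on unplaced or unlocalised contigs, including 5 on a contig assigned to chromosome 4, with signals from 4.46 to 15.6, and 3 on a contig assigned to the X chromosome, with signals of 14.1, 3.74 and 8.19.

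On the assembled chromosomes, 18245 peaks of the pooled list were outside the replicated list, covering 4.75 Mb with a median width of 231 bp and a median signal of 2.59. Of these, 9.94% lay within 1 kb of a TSS and 11.6% had a −log10 q of 5 or more. Peaks of both replicates touched 122 of them, and 7341 touched no peak of either replicate. No biological explanation was tested for either result, since the design held a single group.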

How the results depend on the processing

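The settings that kept 1 member per 100 kb, joined peaks within 1 kb for breadth, or began distal coverage at 5 kb were chosen after the results were seen, the others before. Of the 13 lists called on marking, the erythroid, germline and olfactory receptor lists kept their call in all alternatives run, and so did blood progenitor, erythroid, hepatoblast and housekeeping genes of 9 on breadth, and embryonic globin, erythroid and hepatoblast genes of 6 on distal coverage. The embryonic globin distal call rests on 3 genes, of which Hbb-bh1 and Hbb-y share the same covered bases. The cause of the changes below was not tested unless stated. What depth limits could not be examined, since no depth was known. No setting run turned the direction of the erythroid, hepatoblast or blood progenitor calls on breadth or distal coverage.

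With only peaks of −log10 q of 5 or more, replicate 1 kept 35067 peaks, the overlaps of replicate 1 and replicate 2 rose to 90.9% and 87.9% (Jaccard 0.826), and for the strongest 20000 peaks of each to 95.3% and 95.6% (Jaccard 0.852). Asking for 50% of a peak lowered them to 75.7% and 76.1%, and for 50% of both peaks to 63.3% and 65.1%, a stricter rule by construction. Spearman rho was 0.834 on −log10 p and 0.947 over peaks sharing 50%. At 50% overlap, 11.2% and 10.9% of peaks in a single replicate lay at a TSS. The 50% overlap tried as a rule for the replicated list was met by 92.6% of its peaks when either peak could give the share. As 3069 listed peaks did not meet it, it is not the full rule.

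Promoter summits were 6.04 times the expected share in the pooled list, 7.85 at −log10 q of 5 or more, and 6.63 to 6.69 in a replicate alone, and intergenic summits 0.381, 0.343 and 0.355 to 0.356. Marked genes were 68.9% in the pooled list, 67.2% at −log10 q of 5 or more, 67.9% to 68.0% in a replicate alone, 65.0% with the first TSS only, 66.8% within 500 bp and 68.4% within 2 kb. In the lowest CpG decile 4.44%, 3.07% and 3.48% to 3.62% were marked in the pooled list, the stricter peaks and a replicate alone, and in the highest 99.45% (pooled), 99.36% (stricter) and 99.40% to 99.45% (a replicate alone). Downstream summits were 69.9% in the pooled list and 69.3% to 70.0% in a replicate alone. The widest region was 21162 to 26517 bp in a replicate alone and 51232 bp with peaks within 1 kb joined, and regions of 10 kb or more numbered 33 to 39 and 251.

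Against random lists matched on CpG, 3 lists were above and 3 below on marking. There the mature hepatocyte (30.4%), macrophage (31.2%) and lymphoid shares (38.9%) lay above the matched median and the call ended. The megakaryocyte share (61.5%) also turned from below to above and the Hox share (71.8%) from above to below, and both became calls. These values are the lists' own and the reference changed. Hepatoblast marking ended within 500 bp (75.9%).

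For breadth, 1 list was below in a 10 kb window, where Hox genes (2375 bp) lost their call, and 1 against unmatched lists, where neural (1573 bp) and Hox genes (1428 bp) lost theirs. Unmatched lists also placed embryonic globin (1343 bp) and megakaryocyte genes (1924 bp) below the random median, and within 2 kb embryonic globin genes had 0 bp. The macrophage value in the pooled list was 259 bp, now above its reference. With 1 member per 100 kb, 6 Hox genes had 1745.5 bp and 2 embryonic globin genes 1577.5 bp, both without a call, with fewer genes tested. For distal coverage, 1 list was below at 20 kb (cholangiocyte), 1 at 100 kb and 1 against unmatched lists (olfactory receptor in both). Blood progenitor genes lost their call at 100 kb (9956 bp), and housekeeping genes lost theirs with coverage begun at 5 kb (1798 bp against 709 bp in matched lists). Hox genes gained a call above their reference in the pooled list, on marking (84.6%) and on distal coverage (6235 bp), and at 100 kb (12943 bp).

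Within 100 bp of the summit, 4 motifs were above controls, HNF4 (odds ratio 1.26) and FOXA (1.04) lost their calls, and GATA (0.837) and CTCF (0.484) turned below controls. Controls at 100 bp were not matched on GC. HNF1 passed in the pooled list (2.34) and in either replicate alone (1.79 to 2.23).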

Other observations

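The gene groups and motif positions in the next 3 paragraphs, and the tests of promoter CpG, of neighbouring Hox genes, of the caller's threshold and of the fold left beyond 5 kb after them, were chosen after the results were seen. All 9 genes of heme synthesis were marked in the replicated list and in each replicate, a share above that of all other genes (Fisher's exact test, adjusted p = 0.0454) but not different from the 88.9% of CpG-matched lists (permutation adjusted p = 0.184). They had a median of 6717 bp covered within 5 kb of the TSS against 2645 bp in matched lists (permutation adjusted p = 0.0005, the smallest over 10 groups) and 11225 bp of distal coverage against 2980 bp (permutation adjusted p = 0.0048). Hmbs (9817 bp) and Fech, the ferrochelatase (9314 bp), were broadest, and Alas1 (2704 bp), the form of the first enzyme used outside red cells, was narrower than Alas2 (5476 bp), the red cell form. Hmbs, Alas2 and Fech also belong to groups described above. Plasma protein groups made by hepatocytes were marked above genes of like CpG: coagulation genes at 11 of 16 against 31.2% (permutation adjusted p = 0.0030), with 4898 bp at F2, prothrombin, and complement genes at 10 of 15 against 26.7% (permutation adjusted p = 0.0016), with 7584 bp at C2. Coagulation marking was 14 of 16 in replicate 1 and 10 in replicate 2, and complement marking 9 and 10 of 15. Median breadths were 2191.5 and 1282 bp, each against 0 bp in matched lists (permutation adjusted p = 0.0008 and 0.0207). These breadth calls can largely repeat the marking calls, since breadth among marked genes alone was not compared. Neither share in the replicated list differed from that of all other genes (Fisher's exact test, adjusted p = 1.00 for both), nor did distal coverage from matched lists (permutation adjusted p = 0.153 and 0.168). F2, Fga, Fgb and Fgg are also members of the hepatoblast group. F9, coagulation factor IX, had 0 bp.

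Gene families differed in the extent of the mark. Ribosomal protein genes (76 of 79 marked) had a median breadth of 4492 bp against 3280.5 bp and replication-dependent histone genes (61 of 67 marked) 6433 bp against 3408 bp (both permutation adjusted p = 0.0005). The ribosomal share marked did not differ from matched lists (permutation adjusted p = 0.554). The histone share marked, 91.0%, was below the 97.0% of matched lists (permutation adjusted p = 0.00514) but above that of all other genes (Fisher's exact test, adjusted p = 1.39e-05). Histone genes lie in clusters and share covered bases. Zinc finger genes of the Zfp series were marked at 323 of 365 against 80.5% in matched lists (permutation adjusted p = 0.0005) but had less distal coverage, 1883 bp against 2773 bp (permutation adjusted p = 0.0010), and their breadth, 2219 bp against 2353 bp, did not differ (permutation adjusted p = 0.221). Clustered protocadherins were marked at 18 of 54 against 72.2%, keratins at 6 of 53 against 43.4% and vomeronasal receptors at 1 of 326 against 7.36% (each permutation adjusted p = 0.0005). Random lists were drawn gene by gene, so members lying side by side can make these p-values too small. No setting with 1 member per 100 kb was run for these further groups. Cytochrome P450 genes, at 27 of 100 against 25%, did not differ from matched lists (permutation adjusted p = 0.632). Against all other genes, the cytochrome P450, protocadherin, keratin and vomeronasal shares were lower (Fisher's exact test, adjusted p of 4.63e-07 or less). The ribosomal and Zfp shares were higher (Fisher's exact test, adjusted p of 1.2e-09 or less).

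Motif matches were placed unevenly around distal summits. CTCF matches per window were 0.419 times those of control windows in the 50 bp around the summit, 0.930 times from 50 to 100 bp, and 6.91, 9.68 and 6.91 times in the next 50 bp steps out to 250 bp. GATA matches rose from 0.773 times within 50 bp to 1.36 times at 200 to 250 bp, and the composite from 1.13 to 2.24 times. No explanation of this placement was tested.

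Erythroid and hepatoblast genes were covered more broadly around their TSSs than other genes. Promoter CpG content as the whole cause is argued against, since genes of the same CpG were not broader than others: CpG-matched lists had 0 and 814 bp where unmatched lists had 2067 and 2070 bp, a median that at most 1.32% of the matched lists of either group reached. Neighbouring members counted several times can carry little of it, since keeping 1 member per 100 kb left 25 of 27 erythroid and 26 of 29 hepatoblast members. With so few dropped, the lower percentile of 100 could hardly have moved (7309 bp against 528 bp and 3972 bp against 886.75 bp). Gene density was not matched for breadth, so a share from peaks at neighbouring promoters stays open. No biological explanation was tested, since there was a single group, and whether cell number, gene activity or another feature of these genes is behind the breadth stays open.

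Neural and Hox genes were covered less broadly than genes of like CpG, and wide regions called as several peaks are argued against, since with peaks within 1 kb joined the higher percentile of both lists was 0.09. Calls near the caller's threshold stay open. Each replicated peak had the same edges in the pooled list, so that list could not show edges missed near the threshold. Its added peaks raised the Hox share marked from 71.8% to 84.6%. Breadth there was 1644 bp against 2982 bp for neural and 1434 bp against 2960 bp for Hox genes, the higher percentile being 0.03. Separate peaks left out of the replicated list are thus argued against as the cause of the low breadth. Flanks too weak for the pooled list were not measured, and a −log10 q of 5 or more decided nothing, since it left both medians where they were. Whether the Hox result rests on neighbouring genes stays open: 6 members kept apart lay at percentile 2.26 with 1745.5 bp against 3054.5 bp (permutation p = 0.0454, adjusted p = 0.101), and so few members leave it undecided. No biological explanation was tested.

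Housekeeping genes had more distal coverage than genes of like CpG. Gene density as the whole cause is argued against by lists matched on it as well (percentile 99.98, 10574.5 bp against 4917 bp, permutation p = 0.0006, not adjusted). That matching raised the reference from 3466 bp, so density can hold part of the excess. Promoters of noncoding genes as the whole cause are argued against by leaving out bases within 1 kb of any transcript start (percentile 99.38, 5912.5 bp against 2797.5 bp, permutation p = 0.0126, not adjusted). These conditions were not combined. Edges of the regions at the members' own TSSs stay open: with bases within 5 kb of a TSS left out, the median fell from 10574.5 bp to 1798 bp and that of matched lists from 3466 bp to 709 bp (95% of lists within 1705 to 6312 bp before and 0 to 1851 bp after). The fold went from 3.05 to 2.54 and the percentile of 97.06 no longer passed (permutation p = 0.0590, adjusted p = 0.236), the spread of matched lists being wide beside the bases left. No biological explanation was tested.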
